A study of Mus musculus with 34 samples.

How the data were processed

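Total RNA from the lungs of female C57BL/6 mice, 5 to 7 weeks old per the labels, was measured on two-colour Agilent arrays 28 days after a single intratracheal instillation of 18 or 54 µg of 1 of 3 carbon nanotube materials in 40 µl. The materials carry the codes NRCWE-043, NRCWE-044 and NRCWE-045. Per the labels, the RNA came from random sections of frozen lung, and liver and heart were removed at the same necropsy. Lung RNA (200 ng per array) carried Cy5 on every array and a universal reference RNA made from 11 mouse cell lines carried Cy3, so dye and RNA source were never swapped. What the control mice received is not stated in the labels.

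The authors scanned 34 arrays and extracted the spots with Agilent Feature Extraction, version 11.0.1.1 per the file headers. The deposited scanner files give, for each spot, the intensity of the spot and of its local background in each channel, as median pixel brightness, and a processed intensity after the scanner software's background subtraction and dye normalization. Per the file headers, the scanner files also give a log10 ratio of the processed intensities, which was not used here, and flags of 0 or 1 for spots well above background, saturated or irregular. The deposited series table gives log2 Cy5 over Cy3 for 55681 probes on each array, with every array centred near 0, its median lying between -0.04 and -0.00; the steps behind that table are not given in the sources used here. The series table followed the log2 ratio of the deposited spot intensities with a correlation across probes of 0.935 to 0.989 and a slope of 0.875 to 0.979 over the arrays.

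The plan named mean spot signals, but the deposited files hold medians, so medians were used. Background was subtracted with limma's normexp method and an offset of 50, ratios were normalized within each array by loess, control and irregular spots were given weight 0, and repeated spots of a probe were averaged (limma 3.58.1, statmod 1.5.0, R 4.3.3). Each array has 62976 spots, of which 3671 are controls. Of 55681 distinct probes, 27235 were given a gene symbol through their RefSeq accession, which made 20660 named genes. The other 28446 probes carry accessions outside the annotation used here and were tested without a name. Of each named gene the probe with the highest mean Cy5 intensity was used, and of each unnamed accession likewise. For 45 of the genes named by the rule below another probe was also tested, which gave 80 values, and 10 of them, in 8 genes, were opposite in sign to the probe used; where a value printed against the controls differs by over 1.5 times or in sign, the other probe is given beside it. Units well above background in Cy5 on at least 3 arrays were tested, which left 29316, and 113 probes had a missing value on some array.

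Between 52.2 and 69.4% of the probes on an array were well above background in Cy5 and between 46.2 and 66.5% in Cy3. The median spot intensity was 102 to 165.5 in Cy5, over a local background of 69 to 78, and 67 to 101.5 in Cy3, over a background of 20 to 26. No spot was saturated (0 in either channel), and 0.398 to 0.631% were irregular. No 2 arrays were identical (0 pairs). The method was tested on simulated arrays, in which known changes were added to independent normal noise with each gene's mean and residual spread. They held no slide effect, outlying array or correlation between genes. Of genes given a 1.5-fold change, 68.7 to 76.1% were recovered in a comparison of 5 or 6 arrays with the 5 controls. In that of 3 arrays 71.6% were, and of genes given a 4-fold change 100% were.

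Groups were taken from the sample labels: 5 controls, 5 mice at each dose of NRCWE-043, 6 at 18 and 5 at 54 µg of NRCWE-044, and 3 at 18 and 5 at 54 µg of NRCWE-045. The labels state 5 per group. One control array carries NRCWE-043 and 0 µg in its title and Control as its treatment, and was used as a control. The title of the series names another sample group than the sample titles do, and the design text speaks of more doses than it lists; the treatment and dose of each sample were used. Replicates are numbered in the order of the deposit. The arrays sat on 6 slides, each scanned on its own day; controls were on 4 of them, 2 on 1 slide.

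Each dose of each material was compared with the controls, 54 with 18 µg of each material, and the materials with each other at the same dose, which makes 15 comparisons. A linear model with 7 group means was fitted to each unit and moderated by empirical Bayes in limma, and p-values were adjusted over all 29316 units by the Benjamini-Hochberg method at 0.05. The log2 change of a gene is the difference between 2 group means of its log2 ratio to the reference RNA, printed with its standard error. Lists of marker and pathway genes, 39 in all, were written before the files were opened: 14 pathways, 21 cell types and 4 sources of technical variation, with 751 gene entries, of which 726 were named on the array and 648 tested. Each list was compared with the other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the 39 lists, then by camera with the correlation estimated from the data, by fry, and by an exact two-sided permutation test of the list score. A list score is the mean log2 ratio of the list's genes on an array minus the control mean. Each list's genes were also adjusted over the list alone. A list is said to have shifted where camera with the preset correlation called it, and no gene is said to have changed unless its adjusted p passed. Genes of the lists overlap in function with other cell types, so a list's name states which genes it holds and not which cells were present.

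Genes were named by a rule fixed before the data were examined: for each comparison with the controls, the largest rises and falls past the threshold (10 and 5 at 54 µg, 5 and 3 at 18 µg), up to 4 members with the lowest p of each list described, and 13 genes chosen from what is known of lung responses to nanotubes; for each other comparison, the 5 genes with the lowest p past the threshold, or the 3 with the lowest p where none passed. Clone and predicted gene names were left out. The lists, the comparisons and the alternatives below were also chosen before the data were examined, except where said. The alternatives were the scanner software's processed intensities, no background subtraction, the deposited series table, no filter on dim probes, a filter at 17 arrays, quantile scaling of mean intensities between arrays, all probes tested, each array left out in turn, only the 2 groups compared, slide as a fixed or random block, a 1.5-fold threshold, Cy5 alone, trended and robust moderation, the other set tests, and the controls split 3 against 2 in each of 10 ways. A further 3 alternatives were chosen after seeing the data: marker scores of cardiac muscle, fat, liver and skeletal muscle as covariates, the fit without the 5 arrays with a fat or liver score over 1.5, and the exact permutation of list scores. No paired analysis was possible because each mouse gave 1 array and the labels link no mouse of one group with a mouse of another.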

Results

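The lung transcriptome was measured on 34 two-colour arrays, 1 per mouse, 28 days after a single intratracheal instillation of carbon nanotube material NRCWE-043, NRCWE-044 or NRCWE-045. The series was set up to rank how strongly such materials perturb lung pathways. The groups were 5 controls, 5 mice each at 18 and 54 µg of NRCWE-043, 6 and 5 of NRCWE-044, and 3 and 5 of NRCWE-045. Between 52.2 and 69.4% of the probes on an array were well above background in the lung channel. Across genes, arrays of the same group correlated at 0.919 to 0.978. Slide, which was also scan day, accounted for most of the spread on the first principal component (17.9% of the variance, R² with slide 0.79, with group 0.14). The fourth (7.18%) followed group (R² 0.481) more than slide (0.0692). Each comparison is therefore also given with slide as a block where that changed a call described here. The clock, immediate early, heat shock and hemoglobin lists were written beforehand as signs of technical variation. Log2 changes are given with their standard error (SE).

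At 54 µg the question was which lung genes each material shifted and which shifts were shared. Camera with the preset correlation called 9 gene lists up and 2 down with all 3 materials against the controls. None of these 33 calls (11 lists in 3 comparisons) held with an estimated correlation, where the adjusted p ran from 0.147 to 0.611. The shared upward lists were those of macrophage lysosome and lipid handling, monocytes and interstitial macrophages, CC chemokines and receptors, inflammatory cytokines and the inflammasome, MHC class II presentation, B and plasma cells, T cells, natural killer (NK) cells and cholesterol synthesis. Trem2, the lipid-sensing receptor of foamy macrophages, had log2 changes of 0.85, 0.98 and 0.76 for NRCWE-043, NRCWE-044 and NRCWE-045 (SE 0.31 each, n = 5 against 5). The lysosomal protease Ctss had 0.64, 0.71 and 0.47 (SE 0.21). Ms4a1, the B cell antigen CD20, had 0.72, 0.76 and 0.74 (SE 0.30), and the T cell kinase Lck had 0.48, 0.57 and 0.56 (SE 0.21). The lymphoid homing receptor Ccr7 had 0.60, 0.64 and 0.53 (SE 0.25), and H2-Oa, which tunes peptide loading on MHC class II, 0.39, 0.50 and 0.42 (SE 0.21). The downward lists were those of endothelial cells and fibroblasts. Prx, a scaffold protein of alveolar capillary endothelium, had -0.37, -0.24 and -0.40 (SE 0.13), and Col13a1, a collagen of alveolar fibroblasts, had -0.31, -0.41 and -0.44 (SE 0.16).

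All 33 calls remained with slide as a block. With 4 tissue scores as covariates 27 did: the fibroblast call ended with each material (test direction up for NRCWE-045), the endothelial call with NRCWE-044 and NRCWE-045 and the cholesterol call with NRCWE-044. Across genes, which are not independent replicates, the log2 changes correlated at 0.577 (NRCWE-043 and NRCWE-044), 0.514 (NRCWE-043 and NRCWE-045) and 0.619 (NRCWE-044 and NRCWE-045). Simulations sharing only the controls gave 0.501, 0.496 and 0.498 without regard to slide. With slide as a block the data gave 0.563, 0.512 and 0.614. The 20 simulations then gave 0.507 (0.49 to 0.533), 0.507 (0.464 to 0.542) and 0.516 (0.488 to 0.538). Simulated genes were independent, so these ranges are too narrow to judge by. With separate controls per material, the mean over 10 ways to split them was 0.156 (-0.038 to 0.264), 0.0711 (-0.116 to 0.195) and 0.164 (-0.00989 to 0.311).

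Of the lists with no call at 54 µg of any material, 5 had median log2 changes, in the order NRCWE-043, NRCWE-044 and NRCWE-045, as follows. Extracellular matrix and fibrosis genes had 0.06, -0.03 and -0.07, with Col1a1, the main fibrillar collagen, at 0.12, -0.24 and -0.05 (SE 0.20 each) and Timp1, an inhibitor of matrix proteases, at 0.42, 0.09 and 0.19 (SE 0.19). Alveolar type 2 cell markers had -0.01, -0.04 and 0.02, and the surfactant gene Sftpc -0.04, -0.01 and 0.14 (SE 0.20). Alveolar macrophage markers had -0.02, 0.12 and 0.07, oxidative stress genes -0.06, 0.05 and 0.04, and p53 targets 0.01, -0.02 and -0.01.

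**Figure D1:**
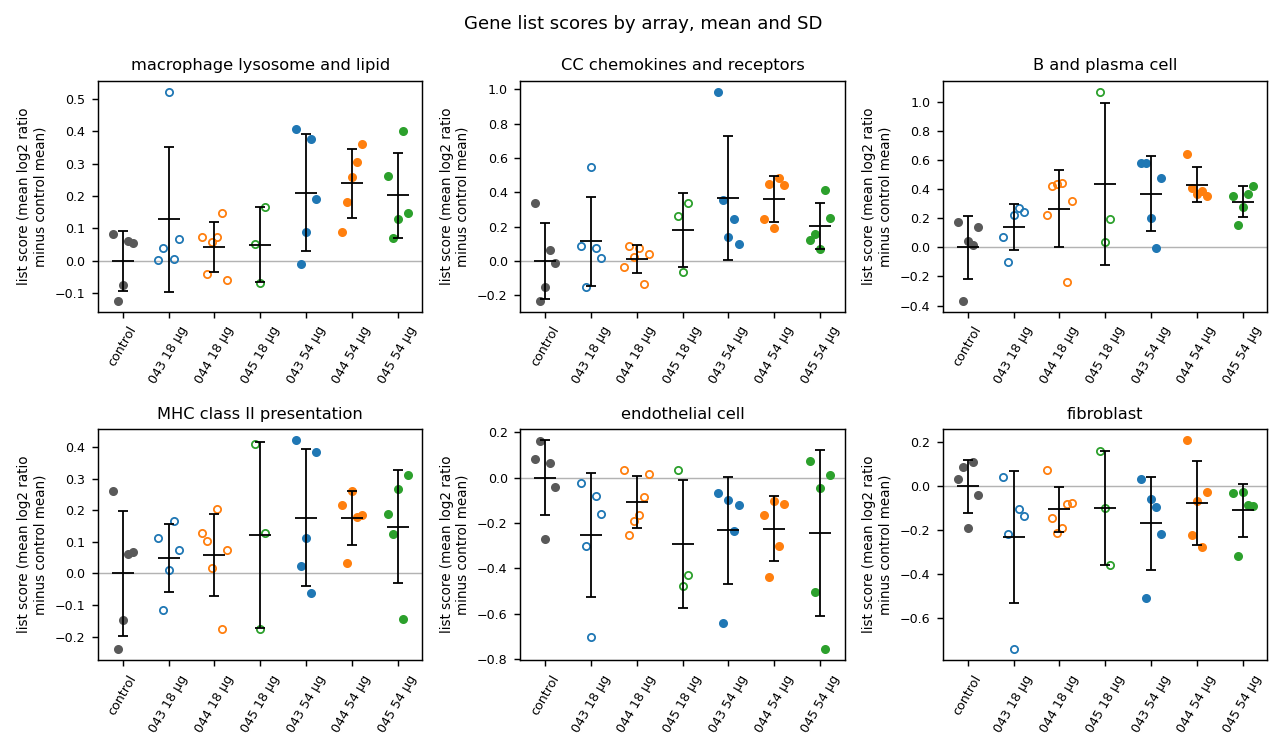
Scores of 6 gene lists on each array (y axis, mean log2 ratio of the list's genes minus the control mean) in the 7 groups (x axis). Points are arrays, open at 18 µg and filled at 54 µg, bars are the mean with SD, and at 54 µg of NRCWE-044 the macrophage lysosome and the B and plasma cell scores lie above every control in 5 of 5 arrays.

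With NRCWE-043 at 54 µg, macrophage, chemokine, interferon and lymphocyte genes lay on average above the controls. The 10 lists described here were not called with an estimated correlation (adjusted p 0.147 for CC chemokines and cytokines, 0.164 for interferon, B cell, lysosome and dendritic genes, 0.315 for the rest). Gpnmb, a glycoprotein of lipid-laden macrophages, had a log2 change of 0.92 ± 0.29 (SE, n = 5 against 5) and the lysosomal protease Ctsd 0.42 ± 0.16 (0.16 by another probe), each with 5 of 5 arrays above every control. The lysosome list they belong to had a median of 0.19 (23 of 30 genes above 0). Among CC chemokines (median 0.26, 19 of 22), the monocyte attractants Ccl9 (0.92 ± 0.29, 5 of 5 arrays) and Ccl2 (0.81 ± 0.31) stood beside Ccr6 (0.63 ± 0.23), the receptor of B cells and Th17 cells. Interferon response genes (median 0.30, 26 of 27) included the RNA sensors Oas2 (1.07 ± 0.26, 5 of 5) and Oas1a (1.13 ± 0.32), the interferon regulator Irf7 (0.89 ± 0.27, 5 of 5) and the ISG15 protease Usp18 (0.66 ± 0.16). B cell genes (median 0.33, 16 of 17) included Ms4a1 (0.72 ± 0.30). Dendritic cell genes (median 0.22, 10 of 12) included the costimulator Cd86 (0.44 ± 0.15). The cytokine list (median 0.19, 19 of 22) held Tnf (0.38 ± 0.16), and the cholesterol list (median 0.12, 19 of 23) held its master regulator Srebf2 (0.43 ± 0.15). The T cell list (median 0.16, 18 of 19) held Lck, and the MHC class II list (median 0.12, 14 of 15) H2-Oa. Endothelial genes lay below the controls (median -0.19, 1 of 18 above 0), among them the endothelin receptor Ednrb (-0.51 ± 0.19) and the junction protein Pecam1 (-0.43 ± 0.19, 5 of 5 below).

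Those 10 lists were called in each of the 10 omissions of 1 array, although replicate 1 gave the interferon score most of its size (1.39, against 0.0547 to 0.295 in the other 4). Without it the medians were 0.127 for interferon, 0.125 for lysosome, 0.114 for cytokine, 0.0859 for T cell and 0.0544 for MHC class II genes, and the CC chemokine score difference was 0.208 in place of 0.364. Other medians that moved by over 1.5 times were those of MHC class II (0.194) and endothelial genes (-0.122) without replicate 2, and of B cell (0.534) and T cell genes (0.259) without replicate 4. Without control replicate 1 they were MHC class II (0.219) and cholesterol (0.0757), without replicate 2 cytokine (0.116) and MHC class II (0.0687), and without replicate 3 dendritic (0.139) and endothelial genes (-0.31). The exact permutation p of the interferon score was 0.182. No single gene passed in limma (0 of 29316, smallest adjusted p 0.337, 1647 at unadjusted p under 0.05 where 1466 are due by chance; with slide as a block 0 and 3326). Without treated replicate 4 the count was 3. Adjusted over the list alone, 8 interferon genes and 2 MHC class II genes passed, and 0 over all genes.

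A further 11 lists were called for NRCWE-043 at 54 µg (adjusted p with an estimated correlation 0.164 for clock genes and 0.315 to 0.472 for the other 10) and each lost its call in at least 1 omission; 5 of them are described here. The others were immediate early (median 0.15; not called with slide as a block, 0.0568) and heat shock genes (0.11), both technical lists, and acute phase (0.09), complement (0.18), alveolar type 1 (-0.19) and club cell genes (-0.22). The monocyte and interstitial macrophage list (median 0.21, 13 of 17 genes above 0) held the macrophage antigen Adgre1 (0.43 ± 0.15) and the Fc receptor Fcgr1 (0.40 ± 0.14). The CXC list (median 0.14, 13 of 18) held the neutrophil attractant Cxcl5 (1.94 ± 0.70) and its receptor Cxcr1 (1.19 ± 0.35, 5 of 5 arrays above every control). The NK list had a median of 0.10. Clock genes (median -0.46, 6 of 16 above 0) held the repressors Nr1d2 (-1.40 ± 0.42) and Per2 (-0.82 ± 0.25) and their output factor Hlf (-0.68 ± 0.19, 5 of 5 below). Fibroblast genes (median -0.17, 4 of 17) held Tcf21, the mesenchymal factor of lipofibroblasts (-1.02 ± 0.23, 5 of 5 below).

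In these 5 lists of NRCWE-043 at 54 µg, 8 clock genes and 1 each of the CXC and fibroblast genes passed adjusted over the list alone. Without treated replicate 1 the CXC (adjusted p 0.316), NK (0.144), monocyte (0.0825) and clock (0.0623) lists were not called. Without treated replicate 2 the fibroblast list (0.0769) was not called, and without control replicate 3 the NK list (0.0847) was not.

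Of the 13 genes chosen beforehand, 12 lay above 0 with NRCWE-043 at 54 µg and 0 passed, adjusted over the 13 alone or over all genes (smallest adjusted p over the 13 0.0596). Saa3, the acute phase apolipoprotein of inflamed lung, had 1.56 ± 0.51 (2 of 5 arrays above every control), the iron-trapping protein Lcn2 0.62 ± 0.29 and the heme oxygenase Hmox1 0.33 ± 0.19. The B cell attractant Cxcl13 had 0.46 ± 0.53, the neutrophil attractant Cxcl1 0.68 ± 0.39, the cytokine Il1b 0.29 ± 0.31, the matrix protein Spp1 (osteopontin) 0.20 ± 0.22 and the alternative activation enzyme Arg1 0.16 ± 0.32. The macrophage elastase Mmp12 (0.22 ± 0.13) was near background, above it in 2 of 5 treated and 1 of 5 control arrays.

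With NRCWE-044 at 54 µg, B cell, chemokine and macrophage genes lay on average above the controls and endothelial genes below them. The 11 lists described here were not called with an estimated correlation (adjusted p 0.267 to 0.33). Jchain, the joining chain of secreted IgA and IgM, had 1.76 ± 0.44 (SE, n = 5 against 5, adjusted p 0.293 in limma), the plasma cell receptor Tnfrsf17 0.52 ± 0.18 and the B cell coactivator Pou2af1 0.72 ± 0.24, each with 5 of 5 arrays above every control. The B and plasma cell list had a median of 0.42 (14 of 17 genes above 0). CC chemokines (median 0.37, 20 of 22) included Ccl9 (0.89 ± 0.29, 5 of 5), the T cell attractant Ccl5 (0.62 ± 0.24, 5 of 5) and Ccl6 (0.59 ± 0.24). The macrophage lysosome list (median 0.19, 23 of 30) included Trem2, Ctss, the collagenolytic protease Ctsk (0.71 ± 0.24) and lipoprotein lipase, Lpl (0.66 ± 0.26, 5 of 5; 0.422 by another probe). Dendritic cell genes (median 0.17, 9 of 12) included the lineage factors Irf4 (0.58 ± 0.16, 5 of 5) and Batf3 (0.54 ± 0.14, 5 of 5). T cell genes (median 0.21, 18 of 19) included Lck and the costimulatory receptor Cd28 (0.35 ± 0.13), and NK genes (median 0.20, 13 of 14) included Eomes (0.40 ± 0.16). Cell cycle genes lay above the controls in 28 of 28 members (median 0.18), among them the proliferation marker Mki67 (0.54 ± 0.27). Monocyte genes had a median of 0.23 (15 of 17) and cholesterol genes 0.14 (19 of 23). Endothelial genes lay below the controls in 18 of 18 members (median -0.22), among them Ednrb (-0.58 ± 0.19, 5 of 5 below). Alveolar type 1 genes had a median of -0.17 (1 of 13 above 0).

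Those 11 lists were called in each of the 10 omissions of 1 array and with slide as a block. Medians that moved by over 1.5 times were those of endothelial genes (-0.139) without treated replicate 2 and of dendritic genes (0.0989) without replicate 3. Without control replicate 1 they were cell cycle (0.289), NK (0.3) and dendritic genes (0.252), and without control replicate 3 NK genes (0.123), where the monocyte score difference was 0.126 in place of 0.211. The exact permutation p was 0.00794 for the lysosome and B cell scores, each above every control in 5 of 5 arrays. No gene passed in limma (0, smallest adjusted p 0.101, 1712 at unadjusted p under 0.05; with slide as a block 1 and 3072). Without treated replicate 4 the count was 13. Of the B and plasma cell genes 3 passed adjusted over the list alone and of the dendritic cell genes 2, and 0 over all genes.

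A further 12 lists were called for NRCWE-044 at 54 µg (adjusted p 0.328 to 0.614 with an estimated correlation) and lost their call in at least 1 omission; 6 of them are described here. The others were heat shock (median -0.14, a technical list), skeletal muscle (0.21), complement (0.11), neutrophil (0.20), eosinophil (0.15) and ciliated cell genes (0.13). Thymus markers, some of them also T cell genes, had a median of 0.15 (8 of 9 above 0; Dntt 0.27 ± 0.15). Interferon genes had a median of 0.16 (20 of 27 above 0; Oas1a 0.92 ± 0.32, Oas2 0.78 ± 0.26). Cytokine and inflammasome genes had 0.10 (15 of 22; the inflammatory caspases Casp4 0.47 ± 0.16 and Casp1 0.40 ± 0.16) and MHC class II genes 0.10 (13 of 15). Type 2 immunity genes (median 0.25, 22 of 27) held the anion exchanger Slc26a4 (1.34 ± 0.63). Fibroblast genes (median -0.18, 3 of 17) held the growth factor receptor Pdgfra (-0.39 ± 0.18). The fat score of replicate 1 of this group was 3.54 and its liver score 1.21.

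In these 6 lists of NRCWE-044 at 54 µg, 1 MHC class II gene passed adjusted over the list alone. Without treated replicate 1 the thymus list (adjusted p 0.101) was not called, without replicate 2 the interferon (0.0701) and fibroblast (0.055) lists were not, and without replicate 4 the fibroblast (0.069) and type 2 (0.0651) lists were not. Of the control omissions, replicate 2 ended MHC class II (0.0636) and cytokine (0.0617), and replicate 3 interferon (0.126). The thymus call also ended without control replicates 1 (0.0631), 2 (0.089) and 4 (0.0785).

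Of the 13 genes chosen beforehand, 10 lay above 0 with NRCWE-044 at 54 µg and 0 passed over the 13 alone (smallest adjusted p 0.357) or over all genes. Saa3 had 1.07 ± 0.51, Cxcl1 0.65 ± 0.39, Lcn2 0.48 ± 0.29, Il1b 0.45 ± 0.31 and Ccl2 0.27 ± 0.31. Cxcl13 had 0.03 ± 0.53, Hmox1 -0.02 ± 0.19 (-0.00849 by another probe), Spp1 0.13 ± 0.22, Arg1 0.12 ± 0.32 and Mmp12, near background, 0.22 ± 0.13.

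With NRCWE-045 at 54 µg, lymphocyte, macrophage lipid and cholesterol genes lay above the controls and heat shock, endothelial and cardiac genes below them. The 10 lists described here were not called with an estimated correlation (adjusted p 0.278 to 0.55). T cell genes (median 0.25, 18 of 19 above 0) included Lck (0.56 ± 0.21, SE, n = 5 against 5) and Cd28 (0.35 ± 0.13). NK genes (median 0.26, 13 of 14) included the death ligand Fasl (0.36 ± 0.17), and B cell genes (median 0.33, 16 of 17) included Ms4a1 (0.74 ± 0.30, 5 of 5 arrays above every control). The lysosome and lipid list (median 0.16, 26 of 30) included Trem2, Ctsk (0.57 ± 0.24) and the cholesterol exporter Abcg1 (0.37 ± 0.14). The cholesterol list (median 0.19, 19 of 23, 7 at unadjusted p under 0.05) included Insig1 (0.41 ± 0.15) and the synthase Hmgcs1 (0.41 ± 0.16). CC chemokines had a median of 0.27 (17 of 22; Ccl5 0.47 ± 0.24) and cytokine and inflammasome genes 0.11 (17 of 22; the adaptor Pycard 0.35 ± 0.14, 5 of 5). Heat shock genes lay below the controls in 11 of 11 members (median -0.29; Hspa1a -0.82 ± 0.33). Endothelial genes did so in 17 of 18 (median -0.22). Cardiac muscle genes had a median of -1.03 (1 of 14 above 0), with atrial myosin Myh6 at -3.47 ± 1.42 (-0.118 by another probe) and sarcolipin, Sln, at -3.07 ± 1.38.

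Those 10 lists were called in each of the 10 omissions and with slide as a block. Without treated replicate 4 the medians were -1.99 for cardiac, -0.102 for endothelial, 0.0751 for cholesterol and 0.124 for CC chemokine genes, and without replicate 1 they were 0.161 for NK and -0.361 for endothelial genes. Without control replicate 1 the cytokine median was 0.17. Without control replicate 2 it was 0.0729, with 0.154 for CC chemokine and 0.12 for cholesterol genes and a heat shock score difference of -0.193 in place of -0.3, and without control replicate 3 the endothelial median was -0.337. No gene passed in limma (0, smallest adjusted p 1, 1152 at unadjusted p under 0.05; with slide as a block 1 and 2026).

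A further 6 lists were called for NRCWE-045 at 54 µg (adjusted p 0.278 to 0.662 with an estimated correlation) and lost their call in at least 1 omission; 5 of them are described here. The other was club cell genes (-0.18; not called with slide as a block, 0.0548). Thymus markers had a median of 0.20 (8 of 9 above 0; Dntt 0.21 ± 0.15). Fibroblast genes (median -0.14, 4 of 17 above 0) held Tcf21 (-0.65 ± 0.23) and Col13a1 (-0.44 ± 0.16). Liver genes (median 0.44, 11 of 11) held the protease inhibitor Serpina1a (0.92 ± 0.58; 0.334 by another probe). Monocyte genes had a median of 0.08 (15 of 17) and MHC class II genes 0.13 (14 of 15). Without treated replicate 1 the liver (adjusted p 0.617) and monocyte (0.117) lists were not called. The same held without replicate 2 for fibroblast (0.0522), without replicate 3 for monocyte (0.104) and MHC class II (0.0999), without replicate 4 for monocyte (0.178), and without replicate 5 for MHC class II (0.0799) and thymus (0.0508). Of the control omissions, replicate 2 ended MHC class II (0.178) and monocyte (0.0694), and replicate 3 monocyte (0.518) and MHC class II (0.124).

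Of the 13 genes chosen beforehand, 10 lay above 0 with NRCWE-045 at 54 µg and 0 passed over the 13 alone (smallest adjusted p 0.607) or over all genes. Saa3 had 1.06 ± 0.51, Cxcl1 0.45 ± 0.39, Lcn2 0.42 ± 0.29, Ccl2 0.28 ± 0.31 and Spp1 0.08 ± 0.22. Il1b had 0.03 ± 0.31, Cxcl13 -0.14 ± 0.53, Hmox1 -0.06 ± 0.19 (0.0285 by another probe) and Arg1 0.01 ± 0.32.

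**Figure D2:**
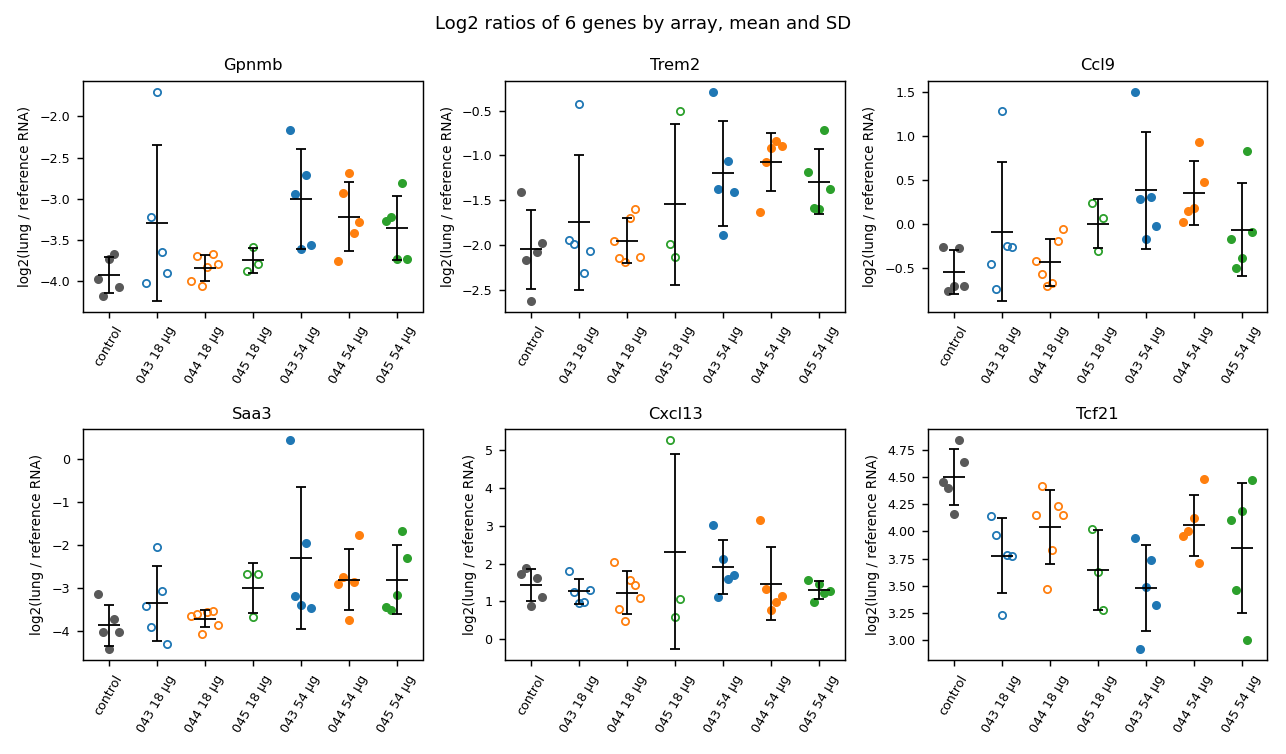
Log2 ratio of lung to reference RNA (y axis) of 6 genes on each array in the 7 groups (x axis). Points are arrays, open at 18 µg and filled at 54 µg, bars are the mean with SD, and in the NRCWE-043 54 µg group Gpnmb and Ccl9 lie above every control in 5 of 5 arrays and Tcf21 below in 5 of 5, while 2 of 5 arrays lie above every control in Saa3.

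At 18 µg, the question was which of these shifts appear at the lower dose, and 1 list, that of T cells, moved up with all 3 materials. The T cell list had medians of 0.12, 0.22 and 0.14 for NRCWE-043, NRCWE-044 and NRCWE-045, and was not called with an estimated correlation (adjusted p 0.573, 0.632 and 0.844). Lck had 0.36 ± 0.21, 0.45 ± 0.20 and 0.61 ± 0.25. Saa3 had 0.52 ± 0.51, 0.16 ± 0.49 and 0.86 ± 0.59, Ccl2 0.19 ± 0.31, -0.21 ± 0.29 and 0.15 ± 0.35, and Sftpc 0.06 ± 0.20, 0.28 ± 0.19 and 0.14 ± 0.23. Of the 13 genes chosen beforehand 10, 4 and 10 lay above 0 and 0 passed over the 13 alone (smallest adjusted p 0.971, 0.897 and 0.16) or over all genes. The T cell calls held with slide as a block.

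With NRCWE-043 at 18 µg, cholesterol and cytokine genes lay above the controls, as did the immediate early genes, a technical list, and cardiac, airway secretory and endothelial genes below them. The 6 lists described here were not called with an estimated correlation (adjusted p 0.209 for immediate early genes and 0.443 to 0.501 for the rest). Immediate early genes (median 0.33, 14 of 15 above 0) included Atf3, a stress-response repressor (0.54 ± 0.14, SE, n = 5 against 5), the orphan receptor Nr4a1 (0.92 ± 0.38) and Fos (0.57 ± 0.27). Cholesterol genes (median 0.17, 20 of 23) included Srebf2 (0.46 ± 0.15), and cytokine genes (median 0.13, 18 of 22) included Tnf (0.27 ± 0.16). Club cell genes lay below the controls in 18 of 18 members (median -0.38), among them the secretoglobin Scgb3a1 (-1.58 ± 0.71), the airway protein Bpifb1 (-1.78 ± 0.82) and the mucin Muc5b (-1.39 ± 0.69). Endothelial genes did so in 18 of 18 (median -0.26; Ednrb -0.40 ± 0.19). Cardiac muscle genes did so in 14 of 14 (median -1.27; Sln -2.50 ± 1.38, myoglobin Mb -1.86 ± 1.03).

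Those 6 lists and the T cell list were called in each of the 10 omissions. Without treated replicate 3 the medians were 0.058 for cytokine, 0.0974 for cholesterol, -0.201 for club cell and -0.171 for endothelial genes, without replicate 1 that of club cell genes was -0.634, and without replicate 2 that of T cell genes was 0.205. Without control replicate 2 the cholesterol median was 0.107, and the score differences were 0.0744 in place of 0.117 for cytokine and 0.0849 in place of 0.137 for T cell genes. Without control replicate 3 the cytokine median was 0.079. The exact permutation p was 0.0318 for immediate early and 0.0476 for cardiac genes. No gene passed in limma (0, smallest adjusted p 0.274, 1276 at unadjusted p under 0.05; with slide as a block 0 and 1939). Adjusted over the list alone, 1 immediate early gene did.

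A further 8 lists were called for NRCWE-043 at 18 µg (adjusted p 0.443 to 0.699 with an estimated correlation) and lost their call in at least 1 omission; 3 of them are described here. The others were clock (median -0.29, a technical list), fat cell (-0.75), ciliated (-0.22), smooth muscle (-0.14) and cell cycle genes (0.09). The lysosome and lipid list (median 0.11, 20 of 30 above 0) held the lipid droplet protein Plin2 (0.48 ± 0.12). The extracellular matrix list (median 0.08, 25 of 38) held the crosslinking enzyme Loxl1 (0.55 ± 0.19) and, on the other side of 0, Ccn2 (-0.50 ± 0.17). Fibroblast genes had a median of -0.21 (1 of 17; Tcf21 -0.72 ± 0.23, 5 of 5 arrays below every control).

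In these 3 lists of NRCWE-043 at 18 µg, 1 lysosome gene passed adjusted over the list alone. Without treated replicate 3 the lysosome (adjusted p 0.26) and fibroblast (0.162) lists were not called. The matrix list was not called without replicate 1 (0.0544), 4 (0.287) or 5 (0.0971) or control replicate 3 (0.364).

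With NRCWE-044 at 18 µg, heart muscle and airway secretory genes lay below the controls and lymphocyte genes above them. The 4 lists described here were not called with an estimated correlation (adjusted p 0.489 for cardiac and 0.632 for the other 3). Cardiac genes had a median of -2.00 (0 of 14 above 0). Myh6 had -4.68 ± 1.36 (SE, n = 6 against 5; -0.669 by another probe), Sln -4.19 ± 1.32 and Mb -3.01 ± 0.99. The score lay below every control in 6 of 6 arrays. Club cell genes had a median of -0.26 (6 of 18 above 0), with Bpifb1 at -2.42 ± 0.79 and Scgb3a1 at -1.86 ± 0.68 (each below every control in 6 of 6 arrays) and Muc5b at -1.80 ± 0.66. B cell genes (median 0.19, 16 of 17) included Ms4a1 (0.72 ± 0.28), the B cell receptor chain Cd79b (0.66 ± 0.28) and Pou2af1 (0.56 ± 0.23), and T cell genes (17 of 19) included the receptor chain Cd3g (0.35 ± 0.16).

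Those 4 lists were called in each of the 11 omissions and with slide as a block. The club cell median was -0.405 without treated replicate 1, -0.153 without replicate 4 and -0.408 without control replicate 5, and the B cell score difference was 0.173 in place of 0.265 without control replicate 2. The exact permutation p was 0.00216 for the cardiac and 0.00433 for the club cell score. No gene passed in limma (0, smallest adjusted p 1, 918 at unadjusted p under 0.05; with slide as a block 0 and 1333). Of the cardiac genes 6 did when adjusted over the list alone.

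A further 6 lists were called for NRCWE-044 at 18 µg (adjusted p 0.632 to 0.824 with an estimated correlation) and lost their call in at least 1 omission; 2 of them are described here. Upward were NK genes (median 0.14, 13 of 14; granzyme Gzma 0.43 ± 0.24) and thymus markers (0.21, 8 of 9; Cd8b1 0.23 ± 0.14). The other 4, hemoglobin (0.17, a technical list), fat cell (-0.73), ciliated (-0.14) and smooth muscle genes (-0.08), were not called with slide as a block. Without treated replicate 2, which left 6 lists in all, the NK list (adjusted p 0.053) was not called, nor was it without control replicate 3 (0.0968). The thymus call ended without treated replicate 2 (0.0681) and control replicates 2 (0.0612) and 4 (0.0664).

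With NRCWE-045 at 18 µg, liver genes had the largest median of the 39 lists of this comparison, 1.97 (11 of 11 genes above 0). The list was not called with an estimated correlation (adjusted p 0.153), nor were the other 8 called, of which 5 are described here (0.631 for B cell and acute phase, 0.844 to 0.959 for the rest). Replicate 2 gave most of its size, with a score of 4.05 against 0.9 and 0.384 in replicates 1 and 3, and without it the median was 0.469 and the score difference 0.642 in place of 1.78. Replicates 1 and 2 are among the 5 arrays with a fat or liver score over 1.5. Serpina1a, the antitrypsin of hepatocytes, had 3.16 ± 0.67 (SE, n = 3 against 5, adjusted p 0.202 in limma), albumin, Alb, 2.50 ± 0.58 (0.229) and Ahsg 2.19 ± 0.57 (0.275), each above every control in 3 of 3 arrays. Acute phase genes (median 0.20, mean 0.58, 15 of 19) included Saa1 (0.80 ± 0.25, 3 of 3) and the orosomucoid Orm2 (1.45 ± 0.46). B cell genes (median 0.41, 16 of 17) included Ms4a1 (1.15 ± 0.34, 3 of 3) and Pou2af1 (0.77 ± 0.28). Neutrophil genes (median 0.23, 16 of 19) included the granulocyte growth factor receptor Csf3r (0.72 ± 0.20, 3 of 3). Of the T cell genes 18 of 19 lay above 0. Endothelial genes had a median of -0.33 (1 of 18; Prx -0.39 ± 0.15). Arg1 had 0.97 ± 0.36, Cxcl13 0.87 ± 0.61 and Il1b 0.57 ± 0.36.

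The liver and endothelial lists were called in each of the 8 omissions, with an endothelial median of -0.147 without treated replicate 2 and an endothelial score difference of -0.455 in place of -0.292 without replicate 1. The exact permutation p of the liver score was 0.0179, the smallest that 3 against 5 arrays allow. No gene passed in limma (0, smallest adjusted p 0.202, 2319 at unadjusted p under 0.05; with slide as a block 0 and 3006). Without treated replicates 3, 1 and 2, in turn, the count was 111, 86 and 1. Of the liver genes 11 passed adjusted over the list alone, of the acute phase genes 7, and 1 each of the B cell and neutrophil genes. Without treated replicate 1, which left 5 lists, the neutrophil (adjusted p 0.767, with a median of -0.08), B cell (0.523) and T cell (0.313) lists were not called. Without replicate 2 the acute phase list (0.233) was not, and without replicate 3 (0.0585) or control replicate 2 (0.0837) the T cell list was not.

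**Figure D3:**
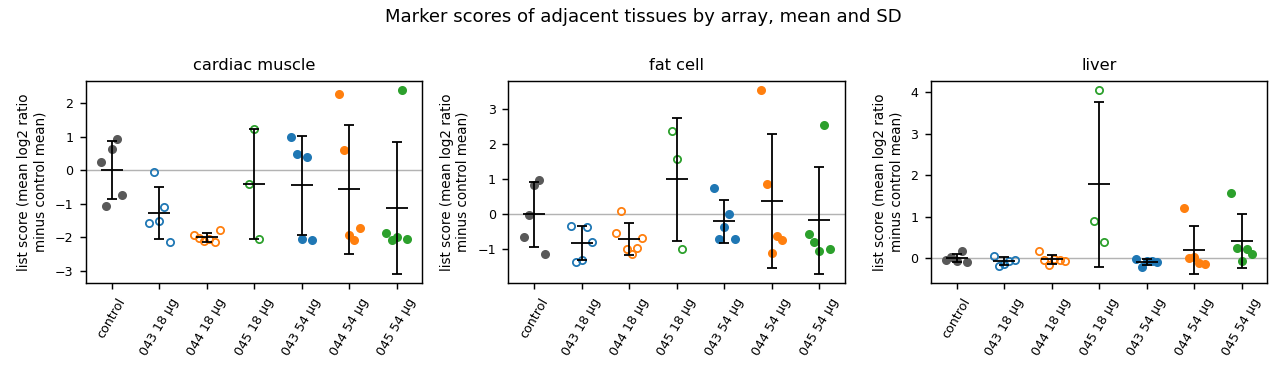
Scores of cardiac muscle, fat cell and liver marker genes on each array (y axis, mean log2 ratio minus the control mean) in the 7 groups (x axis), with points for arrays, open at 18 µg and filled at 54 µg, and bars for the mean with SD. Cardiac scores run from -2.14 to 2.39, fat scores from -1.35 to 3.54 and liver scores from -0.22 to 4.05.

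The doses of each material were compared directly, 54 with 18 µg, to see which genes followed the dose. For NRCWE-044, the macrophage and chemokine genes were higher at 54 µg, in lists called by camera with the preset correlation and not with an estimated one (smallest adjusted p 0.176). CC chemokines had a median of 0.27 and a score difference of 0.35 (95% interval 0.08 to 0.62, n = 5 and 6). Their exact permutation p was 0.00216, 0.0563 adjusted over the 39 lists, and no list passed by permutation (0). The lysosome list had 0.14 (score 0.20, 0.02 to 0.37), the monocyte list 0.20 and the dendritic cell list 0.19. Trem2 had a difference of 0.88 (0.28 to 1.48), Ccl9 0.79 (0.21 to 1.36), Gpnmb 0.62 (0.04 to 1.19) and Saa3 0.91 (-0.09 to 1.90). Trem2, Ccl9 and Gpnmb are named here after their values were seen. Type 2 immunity (median 0.20), interferon (0.17), cholesterol (0.18), eosinophil (0.20), skeletal muscle (0.22), ciliated (0.31), club cell (0.28) and cardiac genes (1.59) also moved up, and alveolar type 1 genes moved down (-0.18). These 13 lists were called in each of the 11 omissions of 1 array, and the other 5 called lost their call in at least 1. Without replicate 1 at 54 µg the medians were 0.743 for cardiac, 0.139 for skeletal muscle, 0.0591 for eosinophil and -0.118 for alveolar type 1 genes. They were 0.133 for eosinophil and -0.109 for alveolar type 1 genes without replicate 2, and 0.0894 for dendritic genes without replicate 3. Without replicates 1, 2 and 5 at 18 µg, in turn, they were 0.457 for club cell, 0.122 for eosinophil and 0.104 for interferon genes. The 3 genes with the lowest p were the neuronal protein gene Zfp365 (-0.44 ± 0.09), Fndc7 (0.54 ± 0.11) and Glipr1 (0.58 ± 0.13), a p53 target of myeloid cells, with adjusted p 0.543 to 0.573.

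For NRCWE-043, interferon genes were higher at 54 than at 18 µg, with a median of 0.33 and a score difference of 0.45 (95% interval 0.10 to 0.81, exact permutation p 0.0238, 0.833 adjusted over the lists, n = 5 and 5). The list was not called with an estimated correlation (adjusted p 0.4), and without replicate 1 at 54 µg the median was 0.197 and the score difference 0.21. Adjusted over the list alone 14 interferon genes passed, and 0 over all genes. Oas2 had 1.11 ± 0.26. B cell genes also moved up (median 0.23, adjusted p 0.702 with an estimated correlation), with a median of 0.151, 0.133 and 0.379 without replicates 1, 2 and 4 at 54 µg and 0.154 without replicate 2 at 18 µg. These 2 lists were called in each of the 10 omissions, and the other 11 called lost their call in at least 1. Saa3 had 1.04 (0.00 to 2.08) and Ccl2 0.63 (0.01 to 1.25), while the lysosome score differed by 0.08 (-0.10 to 0.27). The other genes with the lowest p were the X-linked lymphocyte gene Xlr3b (-1.39 ± 0.32) and the olfactory receptor Olfr850 (-0.36 ± 0.09), which was near background.

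For NRCWE-045, liver genes were lower at 54 than at 18 µg, with a median of -1.53 and a score difference of -1.36 (95% interval -2.32 to -0.41, exact permutation p 0.125, n = 5 and 3). The list was not called with an estimated correlation (adjusted p 0.0817) or without replicate 2 at 18 µg (0.704), which left a median of -0.0943 and a score difference of -0.23. Without replicate 3 at 18 µg the score difference was -2.06. Adjusted over the list alone 10 liver genes passed, and 0 over all genes. NK genes moved up (median 0.20, adjusted p 0.408 with an estimated correlation) and were the only 1 of 9 lists called in each of the 8 omissions, with a median of 0.304 without replicate 4 at 54 µg. Saa3 differed by 0.20 (-1.0 to 1.40). The genes with the lowest p were angiotensinogen, Agt (-0.49 ± 0.12), M1ap (-0.98 ± 0.24) and the urinary protein Mup3 (-1.29 ± 0.33), a hepatocyte product near background.

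Between doses camera called 13 lists for NRCWE-043, 18 for NRCWE-044 and 9 for NRCWE-045. No gene passed in limma for any of the 3 (0 each, smallest adjusted p 1, 0.274 and 1, with 913, 1534 and 699 at unadjusted p under 0.05; with slide as a block 0 each, and 1461, 2057 and 1109). Without replicate 4 of NRCWE-044 at 54 µg its dose count was 3, and without replicate 3 of NRCWE-045 at 18 µg that of NRCWE-045 was 25.

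Comparing materials at the same dose asked which of them was the more potent. At 54 µg, of the 13 genes chosen beforehand only Hmox1 had an interval without 0, between NRCWE-043 and NRCWE-045 (0.386, 95% interval 0.00123 to 0.771, unadjusted p 0.0493). For Saa3, which passed with none of the materials against the controls, the difference was 0.49 (95% interval -0.55 to 1.54) between NRCWE-043 and NRCWE-044, 0.50 (-0.54 to 1.54) between NRCWE-043 and NRCWE-045 and 0.01 (-1.03 to 1.05) between NRCWE-044 and NRCWE-045. For Trem2 it was, in the same order, -0.13 (-0.76 to 0.50), 0.09 (-0.54 to 0.72) and 0.22 (-0.41 to 0.85). For Ccl9 it was 0.03 (-0.57 to 0.63), 0.44 (-0.15 to 1.04) and 0.42 (-0.18 to 1.01), and for the lysosome score -0.03 (-0.21 to 0.15), 0.01 (-0.17 to 0.19) and 0.04 (-0.15 to 0.22). The CC chemokine score differed by 0.00 (-0.28 to 0.28), 0.16 (-0.12 to 0.44; 0.00621 without replicate 1 of NRCWE-043, which ended the call of that list, adjusted p 0.868) and 0.16 (-0.12 to 0.44).

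Between NRCWE-043 and NRCWE-045 at 54 µg, 1 gene passed in limma. Spon2, a secreted pattern recognition protein of the matrix, was higher with NRCWE-043 by 2.46 ± 0.41 (SE, n = 5 and 5, adjusted p 0.029; 2.52 and 0.0421 with slide as a block), with 5 of 5 arrays above every NRCWE-045 array. Without treated replicates 1, 2 or 3 of NRCWE-043, or 1, 2, 3 or 5 of NRCWE-045, the count was 0, and without replicate 4 of NRCWE-045 it was 3. Interferon genes were higher with NRCWE-043 (median 0.38, score difference 0.41, interval 0.06 to 0.77, exact permutation p 0.0476, 11 genes adjusted over the list alone). Their adjusted p with an estimated correlation was 0.159, and without replicate 1 of NRCWE-043 the median was 0.169 and the score difference 0.171. Heat shock genes were higher too (0.48, 6 genes over the list alone), and clock genes were lower (-0.52, score -0.44, interval -0.73 to -0.14, exact permutation p 0.00794, 9 genes over the list alone), with an adjusted p of 0.106 each under an estimated correlation. By permutation adjusted over the lists none of the 3 passed (0.31 to 0.371). These 3 lists were called in each of the 10 omissions, and the other 5 called lost their call in at least 1.

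Between NRCWE-043 and NRCWE-044 at 54 µg, no gene passed in limma (0, smallest adjusted p 0.0825, 1405 at unadjusted p under 0.05; with slide as a block 1 and 2872). The 3 with the lowest p were the acetyltransferase Nat8 (-0.77 ± 0.14, adjusted p 0.0825), Spon2 (2.11 ± 0.41, 0.159) and the ubiquitin ligase Lonrf1 (-0.50 ± 0.10, 0.159). Heat shock (median 0.28) and extracellular matrix genes (0.05, 3 over the list alone) were higher with NRCWE-043, with an adjusted p of 0.324 each under an estimated correlation. Without replicates 4 and 5 of NRCWE-043 the heat shock median was 0.17 and 0.492, and the matrix median ran from 0.017 to 0.128 over the omissions. The other 2 lists called lost their call in at least 1 omission. Between NRCWE-044 and NRCWE-045 no gene passed in limma (0, smallest adjusted p 0.121, 1055 at unadjusted p under 0.05; with slide as a block 0 and 1922). The lowest p were those of Tmem39b (0.37 ± 0.09), the threonine dehydrogenase Tdh (-0.33 ± 0.08) and Usp51 (-0.45 ± 0.11). Of the 10 lists called, 8 lost their call in at least 1 of the 10 omissions, and the other 2, cell cycle and interferon genes (median 0.15 each, higher with NRCWE-044), had an adjusted p of 0.952 each under an estimated correlation.

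**Figure D4:**
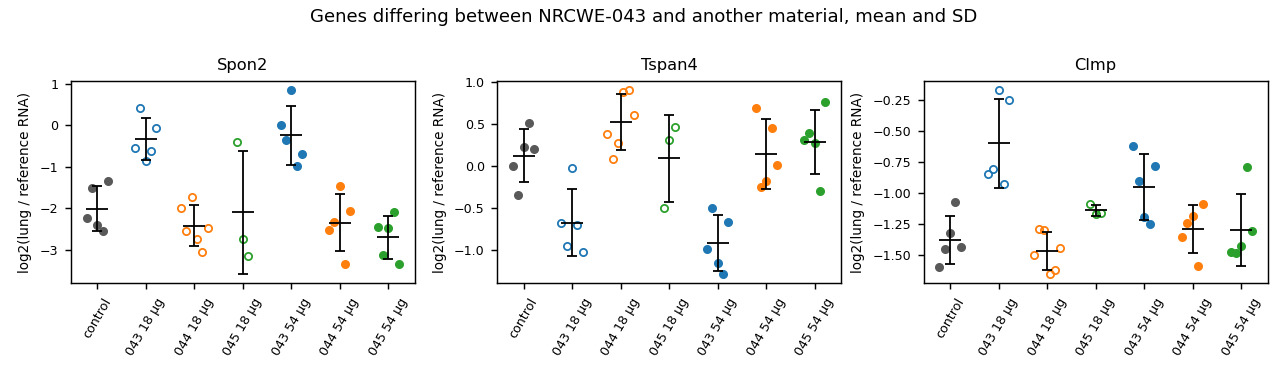
Log2 ratio of lung to reference RNA (y axis) of Spon2, Tspan4 and Clmp on each array in the 7 groups (x axis), with points for arrays, open at 18 µg and filled at 54 µg, and bars for the mean with SD. Spon2 runs from -0.99 to 0.84 in the 10 NRCWE-043 arrays and from -3.34 to -0.40 in the other 24, the highest of these being replicate 1 of NRCWE-045 at 18 µg.

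At 18 µg, 3 genes passed between NRCWE-043 and NRCWE-044 in limma (1630 at unadjusted p under 0.05, 2003 with slide as a block). The adhesion molecule Clmp was higher with NRCWE-043 (0.87 ± 0.14, SE, n = 5 and 6, adjusted p 0.0213). The tetraspanin Tspan4 (-1.19 ± 0.21, 0.043) and Lonrf1 (-0.53 ± 0.09, 0.043) were lower. With slide as a block none passed (Clmp 0.89, adjusted p 0.0696; Tspan4 -1.16 and Lonrf1 -0.50, 0.124). The count was 34 without replicate 1 of NRCWE-044, 1 without replicate 1 or 4 of NRCWE-043, and 0 without replicate 5 of NRCWE-043 or replicate 4, 5 or 6 of NRCWE-044. Cholesterol genes were higher with NRCWE-043 (median 0.19, score difference 0.17, interval 0.00 to 0.33), as were immediate early (0.32) and extracellular matrix genes (0.12, 3 genes adjusted over the list alone), and clock genes were lower (-0.46, score -0.39, interval -0.67 to -0.10, 8 genes over the list alone; -0.331, -0.618 to -0.0445, without Npas2, which was far from the other arrays in replicate 6 of NRCWE-044). With an estimated correlation the adjusted p was 0.111 for immediate early and matrix, 0.122 for clock and 0.284 for cholesterol genes. These 4 lists were called in each of the 11 omissions, with a cholesterol median of 0.108 without replicate 3 of NRCWE-043 and a matrix median of 0.0672 without replicate 5 of NRCWE-044. The other 6 called lost their call in at least 1. Saa3 differed by 0.36 (-0.64 to 1.35).

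Between NRCWE-043 and NRCWE-045 at 18 µg, 128 genes passed in limma, 4 higher and 124 lower with NRCWE-043. Replicates 1 and 2 of the 3 NRCWE-045 arrays are rich in fat or liver transcripts, and the fat score differed too (-1.82, interval -3.58 to -0.07). The count was 6 with the 4 tissue scores as covariates, 71 without the arrays rich in those transcripts, and 0 with Cy5 alone or only the 2 groups compared. Of the 128 genes 64 had a symbol, 102 differed by at least 1.5-fold and 21 passed with slide as a block (3143 and 3407 at unadjusted p under 0.05). The mitochondrial thioesterase Acot2 was higher with NRCWE-043 (0.65 ± 0.12, SE, n = 5 and 3, adjusted p 0.0198). Lower were the lipid desaturase Scd3 (-0.77 ± 0.15, 0.0271) and the hepatic antitrypsin Serpina1c (-2.87 ± 0.56, 0.0271), whose paralogs are near-identical. Liver genes were lower (median -1.81, score -1.85, interval -2.81 to -0.90, exact permutation p 0.0179; 11 genes adjusted over the list alone, 3 over all genes), as were club cell genes (-0.57, 2 over the list alone). With an estimated correlation the adjusted p was 0.292 and 0.699. Without replicate 2 of NRCWE-045 the liver median was -0.28 and the score difference -0.72, and without its replicate 3 the median was -2.72. The other 5 lists called lost their call in at least 1 of the 8 omissions. The count of genes rested on single arrays. It was 0 without replicate 2, 3 or 5 of NRCWE-043 or replicate 2 of NRCWE-045, 430 without replicate 4 of NRCWE-043 and 320 without replicate 1 of NRCWE-045. Saa3 differed by -0.34 (-1.54 to 0.86).

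Between NRCWE-044 and NRCWE-045 at 18 µg no gene passed in limma (0, smallest adjusted p 0.111, 1803 at unadjusted p under 0.05; with slide as a block 0 and 2224). The lowest p were those of Tdh (-0.46 ± 0.09, SE, n = 6 and 3), Serpina1c (-2.76 ± 0.54) and Serpina1a (-3.27 ± 0.65). Without replicates 3, 1 and 2 of NRCWE-045, in turn, the count was 133, 82 and 1. Liver (median -1.88, score -1.81, interval -2.74 to -0.88, exact permutation p 0.0119, 10 genes adjusted over the list alone), acute phase (-0.45, 7) and club cell genes (-0.24, 6) were lower with NRCWE-044. With an estimated correlation the adjusted p was 0.0677 for liver, 0.25 for acute phase and 0.828 for club cell genes. Without replicate 2 of NRCWE-045 the medians were -0.427 for liver and -0.127 for acute phase genes, and the liver score difference was -0.675. The other 6 lists called lost their call in at least 1 of the 9 omissions. Saa3 differed by -0.70 (-1.86 to 0.47).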

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

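The tests of slide as a block on the shared 54 µg lists, of time of day and slide on the genes that set NRCWE-043 apart, and of adjacent tissue and slide on the heart, fat and liver transcripts, and of slide on the splits of the samples were chosen only after the results were seen; those of single mice and of the counts in other splits of the samples were not. The tissue scores tested on the shared lists were also chosen after the results were seen, and the bound for that test was written before its fit was run.

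The first pattern is that immune lists were higher and endothelial and fibroblast lists lower at 54 µg of each material than in the controls. Slide differences are argued against as a source of the calls, since 33 of the 33 remained with slide as a block. So is a single mouse: at least 9 of the 11 calls of a comparison remained when 1 array was left out. Both checks used the preset correlation. RNA of heart, fat, liver or skeletal muscle stays open in part, since 27 of the 33 calls remained with the 4 tissue scores as covariates, and the fibroblast call ended with each material. For NRCWE-045 its test direction reversed to up (adjusted p 0.856, median -0.0739). Thymus markers were called too with NRCWE-044 and NRCWE-045 at 54 µg and with NRCWE-044 at 18 µg. Thymus was not among the 4 scores, so thymus RNA stays open as a source of the lymphocyte genes. The lists may reflect an inflammatory response of the lung to each material, a hypothesis. Chance sharing, not tested, stays open: the 3 comparisons share 5 controls and are not independent. Other splits of the samples called a median of 9 to 12 lists per comparison.

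The second pattern is that Spon2, Tspan4 and Clmp differed between the 10 NRCWE-043 arrays of both doses and the other 24, by 2.05 ± 0.25, -1.05 ± 0.143 and 0.559 ± 0.0965 (log2, SE). The genes were chosen on these arrays, so these values are no test. Single arrays overlapped in each gene (Clmp -1.25 to -0.173 against -1.65 to -0.792). Clmp was lower at 54 than at 18 µg of NRCWE-043 by 0.35 (95% interval 0.05 to 0.65). Slide differences are argued against, since at least 97.1% of each was kept with slide as a block. Time of day at dissection is argued against for Clmp (103% kept with a clock phase score as a covariate). It stays open in part for Spon2 and Tspan4 (smaller share kept 51.6%, 1.38 ± 0.257 and -0.543 ± 0.11). Clock output genes differed in the same arrays (Hlf -0.818 ± 0.115, Tef -0.97 ± 0.169). A response to the material at both doses is the biological explanation that the design gives, and it was not tested apart from these.

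The third pattern is that transcripts of heart, fat and liver differed between arrays of 1 group, as in NRCWE-045 at 54 µg, where replicate 4 had a cardiac score of 2.39 and a fat score of 2.54 (others -2.07 to -1.88 and -1.04 to -0.572) and replicate 1 a liver score of 1.57. Slide differences are argued against, since slide explained at most 18.2% of the variance of a score around the group means, where chance gives 15.3%. Pieces of adjacent tissue in the lung sample are a candidate that no value here tests. The lowest mean pairwise correlation within groups (0.704, fat) is of the genes that showed the pattern. Alb and Ahsg are made in bulk by the liver and Myh6 by the heart, organs removed at the same necropsy. Arrays with positive club cell scores had positive fat scores. The cardiac, club cell and NRCWE-045 liver lists could follow from how each lung was taken, and no biological explanation was tested.

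Of 306 groups examined for an array far from the others, 26 had one, and chance gives about 1 in 20 groups. In NRCWE-043 at 54 µg, replicate 1 had a CXC chemokine score of 1.08, a CC chemokine score of 0.987, an interferon score of 1.39 and a Col1a1 log2 ratio of -2.04, and replicate 2 a thymus score of 0.333. In NRCWE-043 at 18 µg, replicate 3 had a cytokine score of 0.287, a lysosome score of 0.523 and an alveolar type 1 score of -0.388. In NRCWE-044, replicate 1 at 54 µg had a B and plasma cell score of 0.64, a liver score of 1.21 and a Cxcl13 log2 ratio of 3.15, and replicate 5 at 18 µg a B and plasma cell score of -0.24 and a Col1a1 log2 ratio of -3.37. In NRCWE-045 at 54 µg, replicate 4 had a cholesterol score of 0.536, a club cell score of 1.05, a type 2 immunity score of 0.903, a skeletal muscle score of 1.13, a smooth muscle score of 0.242 and a Clmp log2 ratio of -0.792, and replicate 2 a fibroblast score of -0.317. Among the controls, replicate 1 had a cell cycle score of 0.516, replicate 2 a B and plasma cell score of -0.369 and replicate 3 an alveolar type 1 score of -0.206.

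Differences between materials passed the threshold for 1 gene between NRCWE-043 and NRCWE-045 at 54 µg, for 3 between NRCWE-043 and NRCWE-044 at 18 µg and for 128 between NRCWE-043 and NRCWE-045 at 18 µg. Other splits of the same samples were drawn for each comparison. As many genes were called in 5 of 100 splits for the first, in which chance cannot be excluded (highest other 2), in 4 of 100 for the second (highest other 138) and in 2 of 56 for the last (highest other 329). These splits were drawn without regard to slide. With slide as a block the second count was 0, which leaves no call to test, and the last was 21, which 4 of 56 splits reached (highest other 904), so that chance cannot be excluded for either; the first stayed at 1, which 7 of 100 splits reached. For the second and last the highest other split called several times the real count, which points to a structure of the samples besides the material. The split with 138 genes partly followed slide (R² 0.817) and called 0 with slide as a block, and the split with 329 did not lose its calls in this way (904).

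Against the controls, as many lists were called in 1 of 100 splits for NRCWE-044 at 54 µg (real 23, highest other 20, median 9). With slide as a block it was 1 of 100 (real 24, highest other 23). The lowest of 6 unadjusted shares cannot exclude chance. None of these lists was called with an estimated correlation, fry or permutation (0 each, smallest adjusted permutation p 0.155). The count was reached in 5 of 100 for NRCWE-043 at 54 µg (21, highest other 24, median 12). For NRCWE-045 it was in 19 of 100 (16, 23, 10). At 18 µg it was in 16 (15, 19, 8) and 33 of 100 (10, 17, 7) for NRCWE-043 and NRCWE-044. For NRCWE-045 it was in 40 of 56 (9, 23, 11). With slide as a block these were 4, 29, 6, 76 and 37 splits (real 22, 16, 22, 7 and 10). The highest other were 23, 22, 23, 18 and 26. Chance cannot be excluded for these.

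The counts of 0 genes in limma are reached by definition in every split, so the splits say nothing on chance for them: 100 of 100 splits for each comparison with the controls except NRCWE-045 at 18 µg, with 56 of 56, where 1647, 1712 and 1152 genes at 54 µg and 1276, 918 and 2319 at 18 µg had an unadjusted p under 0.05 (with slide as a block 3326, 3072 and 2026, and 1939, 1333 and 3006). The highest other splits called 3, 1 and 0 genes for NRCWE-043, NRCWE-044 and NRCWE-045 at 54 µg and 322, 10 and 2 at 18 µg. Between doses, with 913, 1534 and 699 genes at unadjusted p under 0.05, they called 157, 18 and 116 (100, 100 and 56 splits), between NRCWE-043 and NRCWE-044 at 54 µg 38 and between NRCWE-044 and NRCWE-045 at 54 µg 1 (100 splits each; 1405 and 1055), and between NRCWE-044 and NRCWE-045 at 18 µg 4 (84 of 84 splits; 1803). Splits with 322, 157 and 116 genes beside a real 0, where the median of the other splits was 0, point to a structure of the samples that the groups do not follow. The splits with 322 and 157 genes followed slide (R² 0.8 and 1) and called 0 genes with slide as a block, while the split with 116 did not (R² 0.2) and called 124.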

How the results depend on the processing

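The fits with tissue scores as covariates, those without the 5 arrays with a fat or liver score over 1.5 and the exact permutation of list scores were chosen only after the results were seen. For the counts that moved below the cause was not tested, except where the construction of the setting shows it.

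Among single genes the direction and side of the threshold were kept for all 470 values with no background subtraction, with quantile scaling, with no filter on dim probes and with all probes tested, for 468 with the deposited series table, 467 with trended and robust moderation, 466 with slide as a fixed or random block, 462 with the processed intensities or Cy5 alone, 460 without the 5 arrays, 458 with only the 2 groups compared or the tissue scores as covariates, and all 441 left by the filter at 17 arrays. Of the 94 list calls against the controls, all 94 stayed with no background subtraction, with quantile scaling and with only the 2 groups compared. There were 93 with the series table, 91 with the filter at 17 arrays, 88 with no filter on dim probes, 86 with slide as a fixed and 88 as a random block, 79 with Cy5 alone and 74 with the processed intensities, and 92 with trended and robust moderation. With the tissue scores as covariates 59 stayed, 26 were no longer called and 9 reversed, and without the 5 arrays 80 stayed, 11 were no longer called and 3 reversed. The number of lists called was 0 in each of the 6 comparisons with the controls under an estimated correlation, fry and the exact permutation of scores. The estimated correlation widens the error of a list whose genes move together from mouse to mouse.

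The count of 128 genes between NRCWE-043 and NRCWE-045 at 18 µg was 209 with no background subtraction, 3 with the processed intensities, 0 with Cy5 alone and with only the 2 groups compared. It was 21 with slide as a fixed and 403 as a random block, 6 with the tissue scores as covariates and 71 without the 5 arrays. The 1 gene between the same materials at 54 µg became 0 with the processed intensities, only the 2 groups, trended and robust moderation or the covariates, 4 with slide as a random block and 9 without the 5 arrays. The 3 genes between NRCWE-043 and NRCWE-044 at 18 µg became 1 with the processed intensities, the series table or trended and robust moderation. They became 0 with slide as a fixed and 11 as a random block and 6 without the 5 arrays.

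Counts of 0 also moved. With slide as a fixed block 1 gene was called for NRCWE-044 and for NRCWE-045 at 54 µg against the controls and 1 between NRCWE-043 and NRCWE-044 at 54 µg. As a random block the counts were 8 for NRCWE-044 at 54 µg, 22 between NRCWE-043 and NRCWE-044 and 6 between NRCWE-044 and NRCWE-045 at 54 µg. The last of these was 1 with the processed intensities and 1 with the covariates. Cy5 alone called 1 for NRCWE-045 at 54 µg, and only the 2 groups called 1 for NRCWE-044 at 54 and 5 at 18 µg. With the covariates the counts were 1 for NRCWE-045 at 18 µg, 16 between its doses and 8 between NRCWE-044 and NRCWE-045 at 18 µg. Without the 5 arrays, which leave 1 array of NRCWE-045 at 18 µg that is assumed to vary like the other groups, they were 67, 57 and 67, and 2 for NRCWE-044 at 54 µg. List counts moved for NRCWE-045 at 18 µg, from 9 to 4 with the processed intensities, 15 with Cy5 alone and 16 with the covariates, and for NRCWE-044 at 18 µg, from 10 to 6 with slide as a random block.

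With 1 array left out in turn, the counts of genes against the controls ran from 0 to 3 for NRCWE-043, 0 to 13 for NRCWE-044 and 0 to 0 for NRCWE-045 at 54 µg, and 0 to 0, 0 to 0 and 0 to 111 at 18 µg. The 3 and the 13 were without replicate 4 of the material. The 111 was without replicate 3, with 86 and 1 without replicates 1 and 2. Between doses the ranges were 0 to 0, 0 to 3 (3 without replicate 4 of NRCWE-044 at 54 µg) and 0 to 25 (25 without replicate 3 of NRCWE-045 at 18 µg).

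Between materials with 1 array left out, the counts at 54 µg ran from 0 to 0 for NRCWE-043 and NRCWE-044, 0 to 0 for NRCWE-044 and NRCWE-045, and 0 to 3 for NRCWE-043 and NRCWE-045 (3 without replicate 4 of NRCWE-045, 0 without its replicate 1, 2, 3 or 5 or replicate 1, 2 or 3 of NRCWE-043). At 18 µg they ran from 0 to 34 for NRCWE-043 and NRCWE-044 (34 without replicate 1 of NRCWE-044, 1 without replicate 1 or 4 of NRCWE-043, 0 without its replicate 5 or replicate 4, 5 or 6 of NRCWE-044), 0 to 133 for NRCWE-044 and NRCWE-045 (133, 82 and 1 without replicates 3, 1 and 2 of NRCWE-045), and 0 to 430 for NRCWE-043 and NRCWE-045 (430 without replicate 4 of NRCWE-043, 320 without replicate 1 of NRCWE-045, 0 without replicate 2, 3 or 5 of NRCWE-043 or 2 of NRCWE-045). List counts ran from 16 to 23, 18 to 24 and 14 to 20 at 54 µg and from 11 to 20, 6 to 14 and 5 to 11 at 18 µg, the 6 being without replicate 2 of NRCWE-044 and the 5 without replicate 1 of NRCWE-045.

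Some directions reversed. In NRCWE-044 at 18 µg, Myh11 was 0.42 with the processed intensities and Sftpc -0.11 with Cy5 alone. With the tissue scores as covariates, which removes by construction what follows those scores, the reversed values at 54 µg were Acta1 -0.31, Tnnt3 -0.18 and the skeletal muscle list 0.0095 (test direction down) for NRCWE-044, and for NRCWE-045 the club cell 0.058, fibroblast -0.074 (test direction up), cardiac 0.065 and liver -0.10 lists. At 18 µg they were Kcnj8 0.15, ciliated 0.031 and fat 0.040 for NRCWE-043, cardiac 0.0045 for NRCWE-044, and Fgb -0.18 and liver -0.059 for NRCWE-045. For NRCWE-045 at 18 µg without the 5 arrays, which leaves 1 array and lowers fat and liver genes by construction, Car3 was -1.51, Fabp4 -1.17, Plin1 -0.64, the fat list -0.97, acute phase -0.056 and neutrophil -0.19, and without replicate 1 alone Cxcl13 was -0.61 and the neutrophil list -0.082; over the omissions of single arrays Cxcl13 ran from -0.61 to 1.73 and the neutrophil list from -0.082 to 0.45.

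Changes of genes below background in the lung channel, such as Mmp12, were not resolved.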

Other observations

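The test of the array below against the NRCWE-043 arrays was chosen only after the result was seen.

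Replicate 1 of NRCWE-045 at 18 µg lay with the NRCWE-043 arrays in Spon2, Tspan4 and Lonrf1, and an NRCWE-043 sample under another label is a candidate explanation. Of 50 genes that best part the NRCWE-043 arrays from the rest, chosen without this array, it was nearer to the NRCWE-043 mean in 34. The arrays used to choose them had 34 to 50 (NRCWE-043) and 0 to 24 (others, median 5), so their split is built in. The value lies between the bounds set, so mislabelling and true likeness cannot be told apart. Without this array 86 genes passed between NRCWE-045 at 18 µg and the controls in place of 0.

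Replicate 6 of NRCWE-044 at 18 µg had a log2 ratio of 8.77 for the clock gene Npas2, where the other 33 arrays had -0.138 to 0.983.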
